A study of Mus musculus with 12 samples.

How the data were processed

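Polyadenylated RNA was sequenced from mouse Treg in 12 samples, 6 groups of 2, made up of WT and Kdm2b cKO cells in vivo, unstimulated in vitro and stimulated in vitro. Groups were taken from the sample titles. The authors deposited 2 tables of FPKM, 1 for the 4 in vivo samples and 1 for the 8 in vitro samples. HISAT2 2.2.1 and StringTie 2.1.1 are named, per the submitters' processing notes, which list the builds mm10 and hg19 with no role; which tool made these tables, with which annotation and filters, is not given in the sources used here. FPKM are fragments scaled to gene length and to the fragments of the library, as the authors deposited them, with 1 column per library. The in vivo columns name the genotype but carry no replicate number of the labels, so there the words first and second library only follow the table's order. The tables hold 4 further per-sample columns of no sample in the series, which were not used in any step.

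FPKM are not counts, so no count model was used. Neither total reads nor mapped reads are given, so the depth is unknown and no counting interval was computed. The in vivo table has 16232 genes by Entrez number, of which 16196 were matched to a symbol through the RefSeq annotation. The in vitro table has 24421 genes by symbol, 23204 of them RefSeq symbols and 1096 matched through a synonym. A value of 0 can be a failed estimate, since 1 to 4 of 71 ribosomal protein genes were also at 0 in each in vitro library and 0 to 2 in each in vivo library. A gene at 0 in a group is therefore said to be listed at 0, with each library's value and no fold. Coordinates come from the GENCODE annotation of GRCm38 (mm10), not from the tables.

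Each table was tested separately on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend, two-sided), over genes with a mean of at least 1 FPKM in the samples of the fit. This left 10415 genes in vivo and 10710 in vitro. The 8 in vitro samples were fitted in 1 model, whose 4 groups share an estimate of the spread. Contrasts were cKO over WT in vivo, unstimulated and stimulated, stimulated over unstimulated in WT and in cKO, and the interaction of genotype and stimulation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no minimum fold. Adjusted p-values in the text are limma's for genes and camera's for lists unless another test is named. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The response of the genes induced or repressed by stimulation was measured on genes called for the mean stimulation effect of both genotypes. With groups of equal size that choice favours neither genotype. Fits that left out a library chose the genes anew with unequal groups, where the choice is not neutral between the genotypes.

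The gene lists were fixed before the data were examined, along with the groups, designs and the rule for named genes. Lists with at least 5 tested genes, 37 in each contrast, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, beside camera with an estimated correlation and fry. Calls within a list were also counted with the adjustment over the list alone.

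The rule names Kdm2b, then the 10 largest rises and falls among called genes whose groups do not overlap, whose higher group has a mean of at least 5 FPKM and whose symbol is not a clone, predicted or ribosomal protein name. It adds up to 4 called members of each list, or up to 2 uncalled ones as values, and the PRC1.1 subunits. Where fewer than 5 genes pass in a direction, the 5 with the smallest p are given as values that did not pass. The text gives part of this selection, and of the genes listed at 0 only some; 1 gene that met the rule is not reported here.

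Alternatives set before the data were examined were a pseudocount of 0.1, no filter and a floor of 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling to a common sum (TPM), the replicate number as a block in vitro, robust and trend-free eBayes, only the 4 samples compared, an absolute log2 fold change of at least 1 and leaving out each library in turn. Alternatives and results added after seeing the data are named as such in the closing section. The limma steps were tested on simulated data built from the real means and spreads, with 67, 67 and 66 genes changed by 2, 4 and 8-fold. Of these, 98.5%, 100% and 100% were called in the in vivo design (10341 genes), 55.2%, 98.5% and 98.5% in the unstimulated genotype contrast (10569 genes), 55.2%, 97.0% and 98.5% in the WT stimulation contrast (10592 genes) and 23.9%, 88.1% and 98.5% in the interaction (10552 genes). False calls made up 9.13% of the calls in vivo and 5.26%, 4.12% and 3.18% in the others. The simulated noise was independent between genes and libraries and took its spread from limma's moderated SE. Genes with low means were not among those changed. Recovery in the real libraries may therefore be lower than these shares. A list raised in the simulation was called in each of these designs and 0 of 38 random lists were. Tables were read and figures drawn with Python 3.11.15 and matplotlib 3.10.9.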

Results

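Polyadenylated RNA of mouse regulatory T cells (Treg) was sequenced in 12 libraries, which fall into 6 groups of 2. Treg are the CD4 T cells that restrain immune responses and express the transcription factor Foxp3. The labels give spleen and lymph nodes as the source and separate wild-type mice (WT) from mice with a conditional knockout (cKO) of Kdm2b, which encodes a histone demethylase and a subunit of the non-canonical Polycomb complex PRC1.1. In each genotype 2 libraries came from Treg in vivo, 2 from unstimulated and 2 from stimulated Treg in vitro; the stimulus is not given in the sources used here. The values are FPKM, summing to between 461753 and 475374 per library in vivo and between 369720 and 438763 in vitro. The read depth behind them is unknown, so no interval was computed. Genes listed at 0 numbered 12379 and 13273 in the WT replicate 2 libraries in vitro, unstimulated and stimulated, against 9102 to 9857 in the other in vitro libraries. Nothing in the labels says that replicates came from separate animals or cultures. Each in vivo column name carries its own identifier, but what it stands for is not given. The p-values therefore measure only the spread between these samples, which may be technical.

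The targeted gene, Kdm2b (chromosome 5, 122870665 to 122989823, GRCm38), was measured in every library. Its level in vivo was 112.6 and 110.4 FPKM in the WT libraries and 146.5 and 125.4 in the cKO libraries. Unstimulated in vitro, the WT libraries had 84.9 and 94.9 FPKM and the cKO libraries 89.8 and 97.4. Stimulated, the WT libraries had 74.5 and 71.7 FPKM and the cKO libraries 66.3 and 70.5. The log2 fold change of cKO over WT was 0.28 in vivo (adjusted p = 0.354), 0.06 unstimulated (adjusted p = 0.978) and -0.09 stimulated (adjusted p = 0.778). Stimulated over unstimulated, it was -0.29 in WT (adjusted p = 0.278) and -0.45 in cKO (adjusted p = 0.0977). A conditional allele can remove part of a transcript, and a level over the whole gene cannot show that. These values therefore check no label, and WT and cKO stand below for the libraries labelled so.

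The in vivo comparison asks how Treg differ between the genotypes in the animal. Camk2n1, an inhibitor of the kinase CaMKII, rose in the cKO libraries from 2.15 ± 0.191 to 22.1 ± 0.410 FPKM (SD, n = 2 each), a log2 fold change of 2.87 (SE 0.12, adjusted p = 0.000705). The metallothioneins Mt1 and Mt2, which bind metal ions and whose reads can be shared between them, rose by 2.05 and 2.59 on the log2 scale. Bcor, the scaffold subunit of PRC1.1, rose from 19.3 ± 3.22 to 49.5 ± 6.56 FPKM (log2 fold change 1.32, SE 0.15, adjusted p = 0.0373). Itgb1, the beta 1 integrin chain, fell from 72.7 ± 13.5 to 21.8 ± 3.37 FPKM (log2 fold change -1.69, SE 0.16, adjusted p = 0.0261). In all, 39 of 10415 genes tested with limma were called, 24 higher and 15 lower in cKO.

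**Figure D1:**
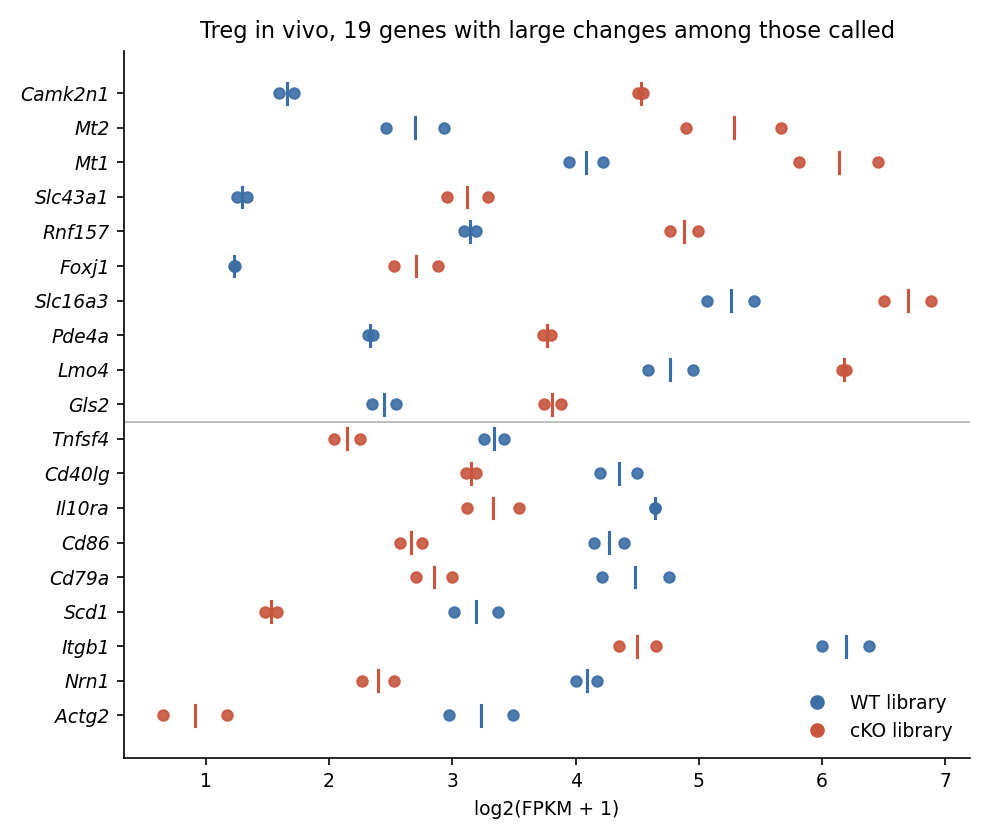
Level of each of 19 genes in the 4 in vivo libraries, as log2(FPKM + 1), for 10 large rises and 9 large falls among the genes called. Points are libraries and short bars group means; in each gene the WT points (blue) and the cKO points (red) lie apart, from Camk2n1 (log2 fold change 2.87) to Actg2 (-2.32).

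Slc16a3, a lactate transporter, rose in vivo from 37.6 ± 7.18 to 104 ± 19.5 FPKM, and Slc43a1, an amino acid transporter, from 1.45 ± 0.0990 to 7.76 ± 1.41 FPKM (n = 2). The log2 fold change was 1.73 for Rnf157, 1.47 for Foxj1, 1.43 for the phosphodiesterase gene Pde4a, 1.41 for Lmo4 and 1.37 for the glutaminase gene Gls2, with adjusted p between 0.0157 for Rnf157 and 0.0353 for Foxj1. The gene that moved furthest had Entrez number 15101 and no symbol in the annotation used here. It was singled out after its values were seen, 1.59 and 1.96 FPKM in WT against 47.7 and 41.7 in cKO (log2 fold change 4.04, adjusted p = 0.000285).

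The co-stimulatory ligand Cd86 fell in vivo from 18.4 ± 2.28 to 5.35 ± 0.552 FPKM (log2 fold change -1.61), and Il10ra, a chain of the receptor for interleukin 10, from 24.0 ± 0.00707 to 9.16 ± 2.09 FPKM (-1.31). The TNF family ligand genes Cd40lg, Tnfsf4, Fasl and Tnfsf8 fell by 1.20, 1.19, 1.05 and 0.98 on the log2 scale, with adjusted p between 0.0261 for Tnfsf8 and 0.0425 for Fasl. Nrn1 had a log2 fold change of -1.69, Actg2 of -2.32 and the fatty acid desaturase gene Scd1 of -1.66. Foxp3 was at 106 ± 0.552 FPKM in WT and 116 ± 2.40 in cKO (log2 fold change 0.12, adjusted p = 0.582). Il10, an anti-inflammatory cytokine, was at 75.0 ± 7.80 and 43.5 ± 0.997 FPKM and did not pass the test (log2 fold change -0.77, adjusted p = 0.0592).

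Transcripts of B cells were lower in the cKO libraries in vivo. Carry-over of B cell RNA into the in vivo libraries was not tested, so a fall of such genes need not lie in Treg. All 15 tested genes of the B cell list had a log2 fold change below 0 (median -1.03). Cd79a was among those called over all genes, at -1.64, and 14 genes were called when adjusted over the list alone. Camera called the list (adjusted p = 3.26e-17), but not with an estimated correlation (adjusted p = 0.933), and fry did not (adjusted p = 0.337). The summed FPKM of the list was 613 and 713 in WT and 276 and 381 in cKO, while haemoglobin genes made up at most 0.00341% of the FPKM of an in vivo library.

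Of the 37 lists tested in vivo, camera called 12 lower and 1 higher. Markers of conventional CD4 T cells had a median of -0.51 (12 tested; 1 called lower, 7 lower and 1 higher when adjusted over the list alone), the Th17 programme -0.44 (15 tested, 0 called) and the Tfh programme -0.29 (13 tested, 0 called). The cytokine list had -0.32 (22 tested, 2 called lower) and chemokines with their receptors -0.32 (20 tested, 0 called). Markers of CD8 T and NK cells had -0.30 and of myeloid cells -0.28, the DNA replication list -0.21, the mitosis list -0.21, early T cell receptor response genes -0.19 and oxidative phosphorylation -0.13, with 0 genes called in each. The cholesterol and lipid synthesis list was called higher, with a median of 0.18 over 25 genes and 1 of them, Scd1, called lower. With an estimated correlation the adjusted p of each of the 13 lists was 0.933, and fry called 0. Over all genes, limma gave 1350 with an unadjusted p under 0.05.

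Of the 10 measured PRC1.1 genes, Bcor was called in vivo. Bcorl1, its homologue, stood at 1.78 ± 0.276 FPKM in WT and 4.57 ± 0.297 in cKO without passing (log2 fold change 1.00, adjusted p = 0.0610). The other 7 subunits apart from Kdm2b lay between -0.34 for Yaf2 and 0.19 for Ring1. The 27 genes of the Treg signature had a median of -0.03 (0.01 with quantile normalization), with 0 called over all genes and, adjusted over the list alone, 6 higher and 5 lower. The pan T cell reference list had a median of -0.06 (camera adjusted p = 0.817). The in vivo count rested on single libraries, being 17 without the second WT library in table order, 425 without the first cKO library and 1994 without the second. It was 0 with no filter on low values, and 11 of 25 named called genes kept their call in each of the 4 fits that left out a library, Camk2n1, Mt1, Mt2, Itgb1 and Cd86 among them.

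The comparison of unstimulated cells in vitro asks the same of Treg in culture. Il10 fell from 49.5 ± 8.38 to 8.53 ± 0.559 FPKM (n = 2; log2 fold change -2.40, SE 0.25, adjusted p = 0.0189). Genes of B cells rose. Cd79b, a signalling chain of the B cell receptor, went from 11.7 ± 2.02 to 69.2 ± 3.28 FPKM (log2 fold change 2.47, SE 0.17, adjusted p = 0.00542), and Cd79a, its partner, from 9.17 ± 0.390 to 57.2 ± 11.4 FPKM (2.50). The tyrosine kinase gene Syk rose by 2.19, the class II gene H2-Ab1 by 1.99 and Scd1 by 2.49 on the log2 scale, with adjusted p of 0.0189, 0.0249 and 0.0189. The haemoglobin gene Hbb-bs, whose reads can be shared with its near-identical copies, was listed at 0 in both WT libraries against 16956 and 1699 FPKM in cKO. Tnfrsf26 was listed at 0 in both cKO libraries against 11.96 and 7.66 FPKM in WT (in vivo 8.33 and 14.15 against 12.61 and 15.51). Together these were the 8 genes called by limma out of 10710 tested, 6 higher and 2 lower in cKO.

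The genes with the next smallest p among those lower in unstimulated cKO cells did not pass. Foxp3 was at 192 ± 3.72 FPKM in WT and 77.0 ± 7.89 in cKO (log2 fold change -1.31, adjusted p = 0.0636), and the chemokine receptor gene Cxcr4 at 369 ± 100 and 142 ± 16.7 (-1.35, adjusted p = 0.0996). The log2 fold change was -2.17 for Atp6v0c, -1.51 for Pde2a and -1.58 for Gpr15. Bcor was at 22.0 ± 6.90 FPKM in WT and 55.7 ± 2.25 in cKO (1.34, adjusted p = 0.143) and Bcorl1 had 0.54 (adjusted p = 0.792). The other 7 subunits of PRC1.1 apart from Kdm2b ranged from -0.41 for Rybp to 0.91 for Pcgf1, with 0 called by limma, where 703 of all genes had an unadjusted p under 0.05.

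Transcripts of other cell types moved with the genotype in unstimulated culture. Haemoglobin genes made up 0.00678% and 0.335% of FPKM in the WT libraries (replicates 1 and 2) and 11.6% and 1.33% in cKO. The B cell list summed to 306 and 557 FPKM in WT and to 1628 and 1431 in cKO. All 16 tested B cell genes lay above 0 (median 2.02), with 3 called over all genes and 16 when adjusted over the list alone. Camera called the list (adjusted p = 4.97e-30), not with an estimated correlation (adjusted p = 0.135), while fry did (adjusted p = 0.0141). Camera also called the erythroid and platelet list (median 2.39, 1 of 14 called), the myeloid list (0.95, 0 of 17 called) and the mitosis list (0.65, 0 of 28 called) as higher. It called as lower the effector Treg list (-0.25, 1 of 37 called, Il10) and heat shock genes (-0.23, 0 of 18 called). With an estimated correlation the adjusted p of these 5 lists lay between 0.791 and 0.894. The Treg signature was not called (median -0.18, adjusted p = 0.104), nor the pan T cell reference list (0.04, and -0.03 with a common sum, adjusted p = 0.984).

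**Figure D2:**
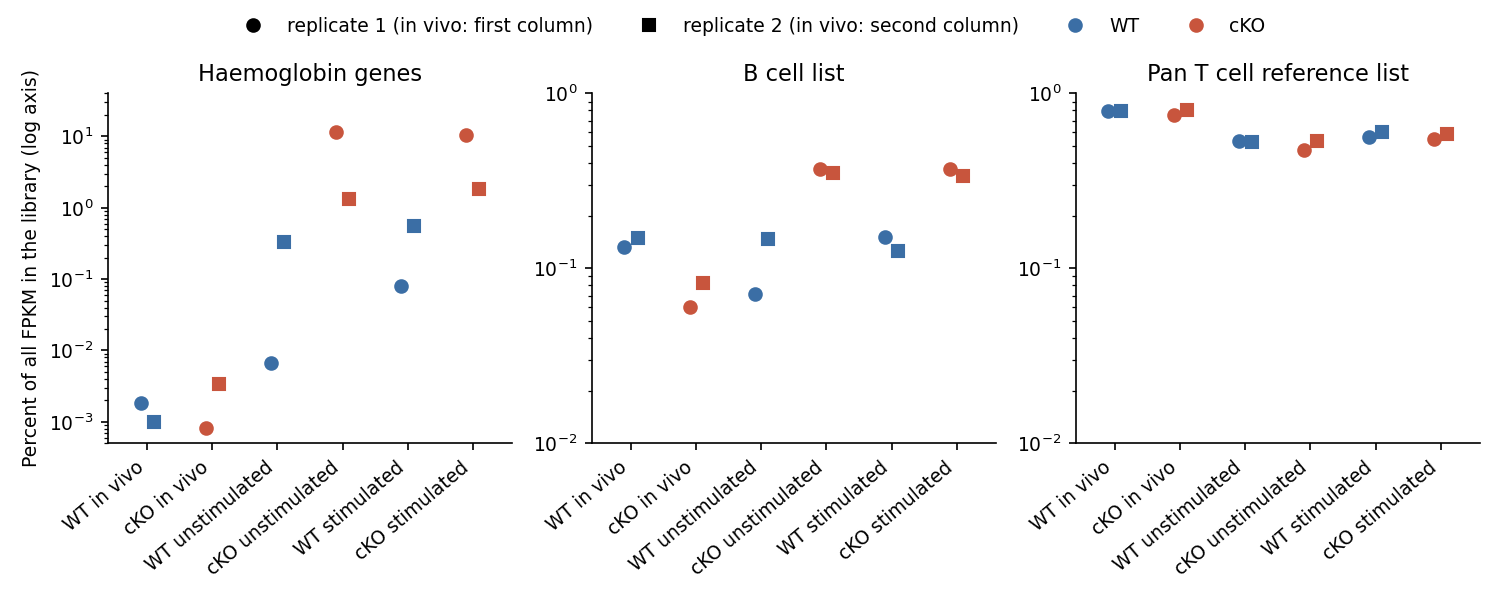
Share of all FPKM in each of the 12 libraries, in percent on a log axis, held by the haemoglobin genes, the B cell list and the pan T cell reference list. Circles are replicate 1 and squares replicate 2 (first and second column in vivo), blue is WT and red cKO; haemoglobin genes reach 11.6% and 10.3% in the cKO replicate 1 libraries in vitro and stay at or below 0.548% in the WT libraries.

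The 8 calls rested on both unstimulated cKO libraries, since limma called 0 genes without either of them. The count was 26 and 28 without WT stimulated replicate 1 and 2, 3 without either stimulated cKO library, 1 with no filter on low values, and, in alternatives chosen after seeing the data, 52 without both WT replicate 2 libraries, 0 without both cKO replicate 1 libraries and 14 with haemoglobin genes removed.

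In stimulated cells, Scd1 rose from 2.36 ± 0.876 FPKM in WT to 17.8 ± 1.05 in cKO (n = 2; log2 fold change 2.51, SE 0.24, adjusted p = 0.0379) and Cd79b from 16.0 ± 1.94 to 61.6 ± 0.940 FPKM (1.89, SE 0.17, adjusted p = 0.0379). These were the only genes of 10710 that limma called between the genotypes after stimulation, while 1508 had an unadjusted p under 0.05. Below that, 5 higher and 5 lower genes are given as values that did not pass. The higher ones were the B cell genes Pax5 (2.96) and Ms4a1 (2.44 ± 0.357 FPKM in WT, 13.7 ± 1.22 in cKO), Syk (1.82), the lysozyme gene Lyz2 (3.35), typical of myeloid cells, and Tbc1d4 (0.98). Cxcr4 was at 198 ± 3.22 FPKM in WT and 54.0 ± 4.07 in cKO (-1.86, adjusted p = 0.0509), and Ccdc22, whose annotated 3' end overlaps that of Foxp3, at 32.2 ± 0.198 and 9.71 ± 0.934 (-1.63, adjusted p = 0.0659). Med10 had -1.18 and Sntb1 -1.41, and Tnfrsf26 was listed at 9.32 and 5.40 FPKM in WT and at 0 and 0.0191 in cKO. Il10 was at 34.4 ± 1.43 and 10.4 ± 3.92 FPKM (-1.68, adjusted p = 0.0864), Bcor at 27.1 ± 3.90 and 57.7 ± 10.3 (1.06, adjusted p = 0.139), and Bcorl1 had 0.40. The other 7 PRC1.1 subunits apart from Kdm2b ranged from -0.73 for Rybp to 0.14 for Pcgf1.

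Camera called 10 lists between the genotypes after stimulation. All 16 tested B cell genes again lay above 0 (median 1.83), with 1 called over all genes and 15 when adjusted over the list alone. Its adjusted p was 6.04e-20, 0.285 with an estimated correlation and 0.0267 with fry. Haemoglobin genes made up 0.0812% and 0.548% of FPKM in the stimulated WT libraries and 10.3% and 1.86% in cKO, and the erythroid and platelet list was called higher (median 2.33), as were the myeloid list (0.65), mitosis (0.54), interferon-stimulated genes (0.38), DNA replication (0.22), cholesterol and lipid synthesis (0.16) and ribosomal protein genes (0.09, but -0.01 with quantile normalization). Heat shock genes (-0.47) and PRC2 subunits (-0.33) were called lower. Scd1 and Cd79b were the only members called over all genes in these lists. With an estimated correlation the adjusted p of the 10 lists lay between 0.285 and 0.907. Without WT stimulated replicate 1 limma called 197 genes, without either unstimulated WT library 8, and without any 1 of the other 5 libraries 0. With libraries rescaled to a common sum the split was 1 higher and 1 lower in place of 2 and 0.

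The response to stimulation was compared within each genotype. In WT cells Il22, a cytokine gene whose reads can be shared with its copy Iltifb, rose from 0.682 ± 0.199 to 162 ± 47.1 FPKM (n = 2; log2 fold change 6.58, SE 0.42, adjusted p = 0.000885). Gpr83, a receptor gene of the Treg signature, rose from 3.73 ± 1.75 to 81.5 ± 27.1 FPKM (4.14), and Socs1, a feedback inhibitor of cytokine signalling, from 23.0 ± 0.221 to 189 ± 21.6 (2.98). Foxp3 rose from 192 ± 3.72 to 613 ± 118 FPKM (1.66, SE 0.17, adjusted p = 0.00439) and Ezh2, the methyltransferase of PRC2, from 16.3 ± 1.62 to 95.8 ± 8.20 (2.49). Bcl6, a repressor that directs the follicular helper programme, fell from 37.9 ± 3.72 to 5.21 ± 0.907 FPKM (-2.65, adjusted p = 0.000978). In all, limma called 260 of 10710 genes, 172 higher and 88 lower after stimulation.

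In cKO cells 490 genes were called, 223 higher and 267 lower. Il22 rose from 1.27 ± 0.759 to 359 ± 204 FPKM (7.22), Gpr83 from 7.52 ± 2.80 to 137 ± 6.13 (4.05) and Socs1 from 21.3 ± 3.85 to 152 ± 8.58 (2.79). Foxp3 rose from 77.0 ± 7.89 to 253 ± 21.2 FPKM (1.70, SE 0.17, adjusted p = 0.00363) and Ezh2 from 16.0 ± 1.25 to 76.2 ± 10.7 (2.17), while Bcl6 fell from 35.9 ± 4.08 to 5.49 ± 0.0810 FPKM (-2.50). The median gene in this contrast lay at -0.14, and rescaling moved that median up by 0.12 (median of ratios), 0.13 (quantile normalization) or 0.10 (common sum). With it the split of calls changed from 45.5% higher to 67.3% (309 and 150), 61.7% (363 and 225) and 66.8% (229 and 114).

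Genes called in the same direction in both genotypes numbered 128 higher and 63 lower, where independent calls would share 3.58 and 2.195 of the 10704 genes compared. Log2 fold changes correlated across genes at Pearson 0.629 and Spearman 0.586, genes not being independent replicates. The contrasts share no library. Values below are log2 fold changes in WT and in cKO. Among the induced genes called in both were the cytokine genes Lta (2.43 and 2.58) and Csf2 (3.16 and 2.11), the survival gene Bcl2 (2.60 and 2.32), the laminin gene Lama5 (3.59 and 3.37), the transcription factor genes Myc (2.03 and 1.57), Irf4 (1.74 and 1.75), Nfil3 (1.48 and 1.24) and Hif1a (1.30 and 1.35), the receptor genes Il2ra (1.83 and 1.83), Tnfrsf9 (1.15 and 1.21) and Tnfrsf4 (1.02 and 1.03), and Socs2 (2.19 and 1.83). Jarid2 of PRC2 had 1.11 and 0.69. Genes that fell in both were Fam101b (-3.90 and -2.69), Tcf7 (-1.53 and -1.75), a factor of resting T cells, Arl5c (-2.25 and -1.88), Matk (-2.30 and -2.47), Cdkn2d (-1.57 and -1.84), St8sia1 (-1.82 and -1.68) and the inhibitory receptor gene Pdcd1 (-0.92 and -1.08). Further genes named by the rule in WT were Lilrb4a (3.27), Il5 (1.74), Tdrp (-2.45), Tubb2a (-2.25) and H60b (-2.06), of which Lilrb4a, Tubb2a and H60b have closely related copies. In cKO they were Itih5 (4.12), Kcnj15 (3.65), Rrp12 (1.29), Txnip (-2.03) and Ypel3 (-1.95).

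**Figure D3:**
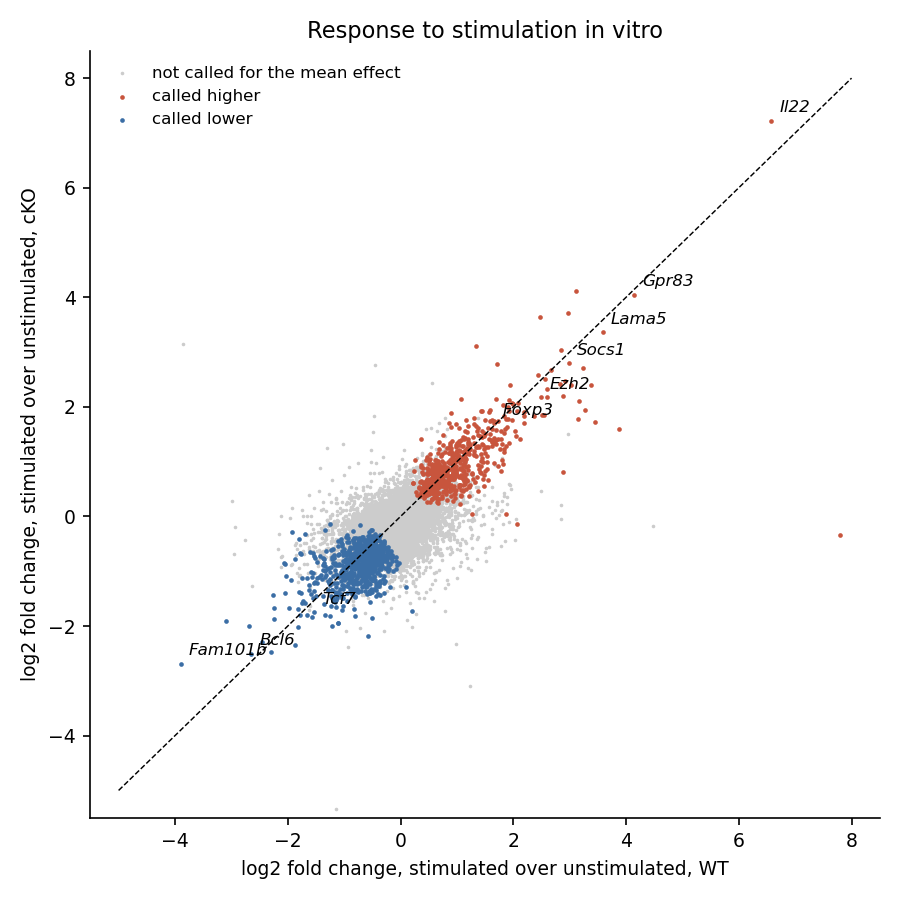
Log2 fold change of stimulated over unstimulated Treg in vitro in WT (horizontal axis) and in cKO (vertical axis), 1 point per gene for the 10710 genes tested. Red and blue points were called higher (580) or lower (750) for the mean of both genotypes, grey points were not, and the dashed line marks equal change; Il22 lies furthest out, at 6.58 and 7.22.

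Lists of known pathways were called with stimulation in both genotypes. Ribosome biogenesis had a median of 0.57 in WT (3 of 30 called, 20 when adjusted over the list alone) and 0.59 in cKO (8 called, 20 over the list alone). Camera called it in both, at 1.24e-12 and 4.36e-17, and with an estimated correlation the adjusted p was 0.0616 in WT and 0.0342 in cKO. The response to interleukin 2 and STAT5 had a median of 1.53 in WT (10 higher and 1 lower of 19) and 1.35 in cKO (12 higher and 1 lower), the lower gene being Bcl6, which that signal is known to repress. Its adjusted p with an estimated correlation was 0.108 and 0.106. Unfolded protein response and amino acid stress genes had 0.61 (4 of 23 called) and 0.55 (6 called), among them the chaperone gene Pdia4 (1.91 and 2.00) and the arginine transporter gene Slc7a1 (1.45 and 1.44). The Treg signature had 0.56 (8 higher and 1 lower of 27) and 0.32 (8 higher). Camera called 17 of 37 lists in WT, 13 higher and 4 lower, and 13 in cKO, all higher. With an estimated correlation the adjusted p of the other lists called lay between 0.108 and 0.771 in WT and between 0.106 and 0.621 in cKO. The lists called lower in WT were ribosomal protein genes (-0.36), resting T cell genes (-0.43), DNA replication (-0.29) and oxidative phosphorylation (-0.29).

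The WT count was 966 without stimulated replicate 1, 95 without stimulated replicate 2, 121 and 119 without the stimulated cKO replicates 1 and 2, 136 without either unstimulated cKO library, and 34 when its 4 libraries were fitted alone. The cKO count was 79 and 12 without unstimulated cKO replicate 1 and 2, 20 without either stimulated cKO library, and 1918 when its 4 libraries were fitted alone.

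The interaction asks whether cKO cells responded to stimulation differently. Limma called 0 of 10710 genes, and 380 (3.55%) had an unadjusted p under 0.05. Among the genes with the smallest p were Slc35b4 (0.89), Hcst (0.84), H60b (1.22) and Myh9 (0.74) above 0 and Dtx3 (-1.42) and Mt2 (-1.84) below, each with an adjusted p of 0.999. In simulated data of this design 23.9% of genes changed by 2-fold and 88.1% of those changed by 4-fold were called. The real share may be lower, since the simulated noise was independent between libraries. The 580 genes induced in the mean of both genotypes had a median response of 0.90 in WT and 0.85 in cKO. Their median interaction was -0.01 beside -0.08 over all genes (camera p = 0.261, and p = 0.621 with an estimated correlation). The 750 repressed genes had medians of -0.67 and -0.81 and a median interaction of -0.12 (camera p = 0.104, and p = 0.666 with an estimated correlation). The first of these medians was 0.08 with median-of-ratios scaling, where camera's p stayed above 0.05, and 0.11 with quantile normalization, where it fell under 0.05, while the median of all genes moved from -0.08 to 0.010 and 0.015. Repressed genes also passed with quantile normalization, at -0.075. Both medians moved when a library was left out. Each such fit chose its genes anew with unequal groups, so that the choice itself can shift the median towards a genotype. The values that follow therefore cannot tell dependence on a library from that choice. Camera's p fell under 0.05 for induced genes without WT stimulated replicate 1 (-0.19), WT stimulated replicate 2 (-0.01), WT unstimulated replicate 2 (-0.15) or cKO unstimulated replicate 1 (0.09), and the sign also turned, without passing, when stimulated cKO replicate 1 (0.0023) or 2 (0.05) was left out. For repressed genes it did so in opposite directions, without WT stimulated replicate 1 (0.28) and without cKO unstimulated replicate 1 (-0.29), and also without stimulated cKO replicate 1 (-0.16) or 2 (-0.20), while leaving out WT unstimulated replicate 2 gave 0.016, which did not pass. Of the lists, ribosomal protein genes had a median interaction of 0.15 (0 of 68 called by limma; camera adjusted p = 0.000892), lost with an estimated correlation (adjusted p = 0.931). Leaving out WT unstimulated replicate 2 gave 1 gene, WT stimulated replicate 1 gave 2 and WT stimulated replicate 2 gave 3.

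The genotype effects were then set side by side. No gene was called in the same direction in vivo and in either culture condition, and at an unadjusted p under 0.05 the shared genes numbered 181 in unstimulated and 210 in stimulated cells. Cd79a and Scd1 were called in opposite directions in vivo and unstimulated, and Scd1 also in vivo and stimulated. The 2 culture conditions shared both stimulated calls, Cd79b and Scd1, where independence gives 0.00112 (Fisher's exact test, p = 2.62e-07). At an unadjusted p under 0.05, genes higher in cKO in vivo and unstimulated numbered 104 (21.8 by independence) and lower ones 77 (18.7). For in vivo and stimulated they were 91 (25.0) and 119 (65.4), and for both culture conditions 177 (17.6) and 145 (28.6). Genes lower in vivo but higher in culture also exceeded independence, at 50 (23.5) unstimulated and 53 (27.0) stimulated. Genes higher in vivo but lower in culture stayed below it, at 5 (17.3) and 40 (60.6). Log2 fold changes correlated across genes at Pearson 0.155 and Spearman 0.170 for in vivo against unstimulated, 0.0884 and 0.0861 against stimulated, and 0.538 and 0.391 between the culture conditions, where B cell and haemoglobin transcripts moved together. Of 23 genes called higher in vivo and measured in vitro, 23 lay above 0 unstimulated and 18 stimulated, and of 15 called lower 10 lay below 0 in each. Over all genes compared, 52.2% lay above 0 unstimulated and 44.1% stimulated, and 47.8% and 55.9% below.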

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

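The tests of explanations for the B cell and haemoglobin pattern were chosen only after the result was seen, while the interaction test of ribosomal protein genes was planned.

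A set of genes moved one way in every cKO library in vivo and the opposite way in every cKO library in vitro, against all WT libraries of the same condition; the difference between the systems was not tested, since the tables were made separately. The log2 fold change in vivo was -1.64 for Cd79a, -0.93 for Cd79b, -1.40 for Fcrl1, -0.99 for H2-Ab1, -1.18 for H2-DMb1, -1.66 for Scd1 and -0.85 for Syk. In unstimulated cells it was 2.50 for Cd79a, 2.47 for Cd79b, 0.58 for Fcrl1, 1.99 for H2-Ab1, 1.09 for H2-DMb1, 2.49 for Scd1 and 2.19 for Syk. In stimulated cells it was 1.27 for Cd79a, 1.89 for Cd79b, 1.33 for Fcrl1, 1.40 for H2-Ab1, 1.67 for H2-DMb1, 2.51 for Scd1 and 1.82 for Syk. Ribosomal protein genes differed in their response to stimulation between the genotypes by camera's test of the interaction, with a median of 0.15 over 68 genes (adjusted p = 0.000892), which did not hold with an estimated correlation (adjusted p = 0.931).

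B cell, haemoglobin and myeloid transcripts were higher in cKO in vitro. A lower share of T cells that raised every other cell type alike is argued against, because the log2 ratio of cKO replicate 1 to replicate 2 was higher for haemoglobin than for B cell genes by 3.33 unstimulated and 2.57 stimulated (mean 2.95). A rise of B cell genes in cKO was not seen in vivo, the median of the B cell list there being -1.03. Carry-over of B cell RNA that differed between the in vivo groups could mask an effect in Treg. A genotype effect that holds in both systems is therefore not decided by this value. RNA of B cells carried over into the cKO libraries stays open. The B-restricted genes (the list without class II genes and Cd74) were higher in the mean of both culture conditions in 12 of 12 cases, but all 16 genes of the list lay above 0 in each condition, which fixes that outcome, so it decides nothing. A genotype effect limited to culture was not tested and stays open, as do the purity of the sort, which is not given in the sources used here, and a separate source for the haemoglobin transcripts.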

How the results depend on the processing

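For 124 fold changes of named genes that had been called, 2338 values were recomputed under the alternatives. Of these 1851 kept direction and call, 487 kept the direction and lost the call (266 of them with 1 library left out) and 0 changed sign. For 35 fold changes of named genes that had not been called, the genotype values of Kdm2b apart, 679 values were recomputed, of which 632 stayed so, 47 were called (27 with 1 library left out) and 0 changed sign. A lone sample left in a group was assumed to vary like the other groups. Unknown depth and 2 samples per group limit every count. For every change below the cause was not tested.

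Leaving out each library in turn, the genes called ranged from 17 to 1994 in vivo (39 with all), 0 to 28 unstimulated (8), 0 to 197 stimulated (2), 95 to 966 for stimulation in WT (260), 12 to 660 in cKO (490), 0 to 3 for the interaction (0) and 7 to 329 for the mean genotype effect (116). Median interactions ranged from -0.19 to 0.089 for induced (-0.01 with all) and from -0.29 to 0.28 for repressed genes (-0.12); below, such a median passed if camera's p was under 0.05, which neither did with all libraries. The lowest and highest median of repressed genes lay on opposite sides of 0. Each fit chose its genes anew with unequal groups, a choice not neutral between the genotypes. These medians therefore cannot show dependence on a library alone. The Kdm2b log2 fold change ranged from 0.17 to 0.39 in vivo, -0.021 to 0.14 unstimulated and -0.14 to -0.050 stimulated. Over all alternatives its sign turned in 2 values unstimulated and 1 stimulated, and it was called in vivo once, at 0.39 without the second cKO library.

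With a pseudocount of 0.1, 0 genes were called between stimulated genotypes, and the median interaction of repressed genes, -0.15, passed. With no filter, 0 genes were called in vivo, 1 unstimulated, 0 stimulated, 92 and 185 for stimulation in WT and cKO and 35 for the mean genotype effect; induced genes had a median interaction of 0.0055 and repressed genes -0.14, which passed. With a floor of 5 FPKM repressed genes had -0.146, which passed. With eBayes without trend 25 genes were called in vivo, 4 unstimulated, 5 stimulated and 157 and 207 for stimulation in WT and cKO. An absolute log2 fold change of at least 1 left 310 genes for stimulation in cKO.

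Median-of-ratios scaling turned the median interaction of induced genes to 0.077, which did not pass. Quantile normalization turned it to 0.11, which passed. With these scalings the median of all genes moved from -0.076 to 0.010 and 0.015, and the induced genes numbered 754 and 801 in place of 580. Quantile normalization also gave 4 stimulated genotype calls, moved repressed genes to -0.075, which passed, and turned Kdm2b in stimulated cells to 0.014 (adjusted p = 0.973; 0.778 before). Rescaling to a common sum turned Kdm2b in unstimulated cells to -0.0034 (adjusted p = 0.999; 0.978 before). Scaling moved some splits of the calls. For stimulation in cKO, 223 genes were higher and 267 lower before, 309 and 150 with median-of-ratios scaling, 363 and 225 with quantile normalization and 229 and 114 with rescaling to a common sum. For the mean stimulation effect, which chose the induced and repressed genes, the split was 580 and 750 before and 754 and 545, 801 and 636 and 721 and 400 in the same order. For the stimulated genotype comparison the split was 2 and 0 before, 3 and 1 with quantile normalization and 1 and 1 with rescaling to a common sum. With only the 4 samples compared, 0 genes were called between stimulated genotypes, 34 for stimulation in WT and 1918 in cKO.

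Alternatives chosen after seeing the data were the following. Where libraries were left out, induced and repressed genes were again chosen anew with unequal groups, so that their medians have the same limit. Without both cKO replicate 1 libraries 0 genes were called unstimulated, 0 stimulated, 32 and 1 for stimulation in WT and cKO and 0 for the mean genotype effect, and repressed genes had -0.35, which passed. Without both WT replicate 2 libraries 52 genes were called unstimulated, 7 stimulated, 1932 for stimulation in cKO, 5 for the interaction and 185 for the mean genotype effect. With haemoglobin genes removed and libraries rescaled 14 genes were called unstimulated and 4 stimulated (2 higher and 2 lower), the mean genotype effect had 85 higher and 31 lower (68 and 48 before), and repressed genes had -0.15, which passed.

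Camera with an estimated correlation called 0 lists in vivo (13 at the preset value), 0 unstimulated (6), 0 stimulated (10), 0 for stimulation in WT (17), 1 in cKO (13), 0 for the interaction (1) and 0 for the mean genotype effect (7). Fry called 0, 1, 1, 9, 5, 0 and 2 in the same order. At an unadjusted p under 0.05 the genotype calls shared in the same direction were counted again. They numbered 181 for in vivo and unstimulated, 210 for in vivo and stimulated, 322 for both culture conditions and 306 for in vivo and the mean genotype effect.

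The in vitro labels share replicate numbers but do not say that a number marks the same animal, culture or day, and 2 numbers are too few to decide it from the values, so a pairing within genotype stays open. Differences between replicates 1 and 2 correlated at 0.24 between WT unstimulated and stimulated and 0.42 between these in cKO, and at -0.14, 0.058, -0.13 and 0.040 across genotypes. Haemoglobin shares in cKO also went with the number, at 11.6% and 10.3% in replicate 1 and 1.33% and 1.86% in replicate 2. With the replicate block 0 genes were called between stimulated genotypes (2 without it) and 2 lists for the interaction (1 without it). That block took a number as common to both genotypes, where the differences correlated little. A block within each genotype was not fitted, and the other tests took the libraries as unpaired. For the in vivo comparison no paired analysis was possible because its columns carry no replicate number of the labels.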

Other observations

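The mean genotype effect over both culture conditions and its test by other splits, the comparison with the in vivo calls, the tests on Foxp3 and the test of haemoglobin on the recurring genes were chosen only after the data were seen. The tests of linkage, of CpG content and of the splits for stimulation were set before their results were seen.

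Averaged over unstimulated and stimulated cells, limma called 116 of 10710 genes between the genotypes in vitro, 68 higher and 48 lower in cKO. Foxp3 had a log2 fold change of -1.29 (SE 0.12, adjusted p = 0.00722), Il10 of -2.04 (SE 0.18, adjusted p = 0.00586), Cxcr4 of -1.60, Gpr15, a homing receptor gene, of -1.62 and Cd200r1, an inhibitory receptor gene, of -1.40. Ces2c had -2.14 and Sytl2 -1.70. Socs2, an inhibitor of cytokine signalling, rose by 1.34, Bcl2 by 0.85 and the developmental transcription factor gene Lhx2 by 1.45. Lyz2 rose by 3.01, Cd79b by 2.18 and Scd1 by 2.50, and 14 of the 16 B cell genes were called, where haemoglobin genes also made up 11.6% and 1.33% of FPKM in unstimulated cKO cells. Of 37 lists camera called 6 higher and 1 lower, of which none held with an estimated correlation (lowest adjusted p = 0.186). The count was 11 and 19 without unstimulated cKO replicate 1 and 2, 7 and 9 without stimulated cKO replicate 1 and 2, 60 and 69 without unstimulated and stimulated WT replicate 2, and 329 without stimulated WT replicate 1.

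Of the genes called in vivo, 7 were called higher and 3 lower in this mean as well, where independent calls would share 0.133 and 0.0716 (Fisher's exact test, p = 3.41e-11 and p = 4.46e-05), and the systems share no library. Values below are log2 fold changes in vivo and in vitro. The higher genes were Bcor (1.32 and 1.20), Camk2n1 (2.87 and 1.15), Slc43a1 (1.83 and 1.86), Rnf157 (1.73 and 0.90), Cd24a (1.11 and 2.19), Utf1 (1.21 and 1.81) and the neurofilament gene Nefm (1.45 and 2.71). The lower genes were Itgb1 (-1.69 and -0.95), Il10ra (-1.31 and -1.13) and Nrn1 (-1.69 and -1.15). In the opposite direction, 3 genes lower in vivo were called higher in vitro, Cd79a and Scd1 among them, where independence gives 0.0869. Of the genes higher in vivo, 0 were called lower in vitro (0.110 by independence). Of 57 genes called higher in the mean and measured in vivo, 29 (50.9%) lay above 0 there, beside 47.3% of all genes compared. Of 47 called lower, 41 (87.2%) lay below 0, beside 52.7%. The shared calls rested on single libraries, and 0 of the 10 genes kept the call in vitro in each of the 8 fits that left out a library. In vitro 0 of the 10 kept it without unstimulated cKO replicate 1, unstimulated cKO replicate 2 or stimulated cKO replicate 2, 1 without stimulated cKO replicate 1, 6 and 4 without unstimulated WT replicate 1 and 2, and 10 and 5 without stimulated WT replicate 1 and 2. In vivo Camk2n1, Itgb1, Nrn1, Rnf157 and Slc43a1 kept the call in each of the 4 such fits, 6 of the 10 genes without the first WT library and 5 without the second.

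These 10 genes form a pattern across both systems. Alleles linked to the targeted locus are argued against as its source, since 0 of the 10 lie within 20 Mb of Kdm2b, beside 3.11% of the genes tested in vivo. Only that locus was examined, so alleles linked to other loci that differ between the genotypes were not tested and stay open. Haemoglobin transcripts that take a share of FPKM would lower other genes in the cKO libraries, so the higher genes could not test that source. With haemoglobin genes removed and libraries rescaled, 9 of the 10 genes kept their call and direction in vitro. This argues against it only for the lower genes that did. RNA of B cells stays open for Cd24a, which B cells also express. An effect of the genotype on the other genes may explain the pattern, as a hypothesis found and tested on the same data.

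Foxp3 was lower in cKO in vitro and at 0.12 in vivo. Dilution of the Treg transcripts by cells without Foxp3 was examined as the whole cause. The other 26 genes of the Treg signature had a median of -0.084 (SD 0.673) against -1.29 for Foxp3. Of these, 17 lay below 0 and 9 above. This argues only against dilution by cells that express none of these genes. Diluting cells may express some of them, so dilution as the whole cause stays open. Foxp3 overlaps Ccdc22 at chromosome X, 7593809 to 7595245 (GRCm38), and the strand of the reads is not given. Reads of Ccdc22 counted for Foxp3 were examined as the whole of the fall. The listed WT level of Ccdc22 was 16.6 and 32.2 FPKM where Foxp3 lost 115 and 360. That is 14.5% unstimulated and 8.93% stimulated, beside an SD of up to 7.89 and 118 FPKM for Foxp3. A listed level omits any Ccdc22 reads that were counted for Foxp3, so it sets no upper bound and decides nothing. Ccdc22 itself had -1.05 in the same mean (limma adjusted p = 0.0177) and 0.03 in vivo. The limit for this comparison was set after the values were seen, an earlier one of under 10% in both conditions having been missed. Shared reads stay open as a part or the whole of the fall.

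It was hypothesised that genes higher in cKO in vivo start in CpG-rich sequence, to which Kdm2b is known to bind. The median CpG ratio of the first 300 bases of their transcripts was 0.744 over the 23 of 24 genes with a value, at percentile 76 of 10000 random lists matched on mean FPKM, which gives the hypothesis no support. The 15 lower genes had a median of 0.417, at percentile 0.02. In the mean of both culture conditions, the median was 0.510 for the higher genes (66 of 68 with a value, percentile 0) and 0.651 for the lower ones (44 of 48, percentile 6.64), so a low ratio was not tied to 1 direction. These 3 comparisons were chosen after their values were seen.

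Other splits of the 8 in vitro libraries were fitted in models without the interaction. For the mean genotype effect 1 of 34 splits, the real one, called as many genes (155, the highest other split calling 1), and for the mean stimulation effect also 1 of 34 (1588, the highest other calling 1). Some of these splits were unbalanced for the other factor and so are not interchangeable with the real split. The result therefore does not exclude a random assignment for either count, even of independent libraries. It also says nothing of what else differs between the groups. Independence is not known, since haemoglobin genes made up 11.6% and 10.3% of FPKM in the unstimulated and stimulated cKO replicate 1 against 1.33% and 1.86% in replicate 2. If the 2 conditions of a replicate number shared a source, fewer splits still would be comparable. The p-values of the mean genotype effect, which count 4 libraries per genotype, would then be too small.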
